A study of Mus musculus with 12 samples.

How the data were processed

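The libraries came from mouse embryonic stem cells (C57BL/6) with fluorescent reporters of Prdm1 (Blimp1) and Dppa3 (Stella). Per the labels' protocols, the cells were kept in a ground-state medium with LIF, cultured 48 h as EpiLCs and then aggregated in PGCLC medium. The labels give day 5 for both PGCLC groups, and PGCLCs positive for both reporters were sorted from dissociated aggregates. For the EpiLC exposure, medium with 100 nM BPA was added 24 h after seeding and left for 24 h; whether BPA was also in the PGCLC medium is not stated. Untreated EpiLC libraries are described as water controls, and the description of untreated EpiLC replicate 3 carries another number and replicate than its title; the title was followed. Libraries were made with a strand-specific mRNA kit (NuGEN Universal Plus), and the strand setting of the counting is not given in the sources used here.

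The submitters' processing notes name bcl2fastq 2.19.1.403, FastQC, STAR and HTSeq and the mm10 build, without versions for the others. The deposited count files hold counts, as whole reads per Ensembl gene, 1 file per library, with genes under 10 counts left out by the authors and with summary rows for reads without a feature (4.42% to 10.7%) and ambiguous reads (4.35% to 6.07%). The deposited tables of CPM, 1 per cell stage (EpiLC 16504 and PGCLC 21473 genes), equal these counts divided by 1 constant per library, with unlisted genes at 0. They were normalised separately, so they served only in an alternative within each stage. Of 21728 genes in any file, 21695 IDs were found in GENCODE M21 (mm10), which gave symbols, coordinates and types. Mitochondrially encoded genes and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were not analysed here.

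Groups were taken from the sample labels: untreated and BPA, EpiLC and PGCLC, 3 libraries each. Every BPA effect was tested within its stage (6 libraries), and the stage difference of untreated cells and the interaction (BPA effect in PGCLCs minus that in EpiLCs) in 1 fit of all 12 libraries with 4 group means. Counts were filtered with filterByExpr, scaled by TMM and tested with the edgeR quasi-likelihood test (R 4.3.3, edgeR 4.0.16), with unlisted genes as 0 and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Every adjusted p of a gene in the text is from edgeR quasi-likelihood with Benjamini-Hochberg, and n = 3 libraries per group. CPM are counts-per-million of the TMM-scaled library. Each fit was scaled on its own, so the same library's CPM can differ slightly between comparisons. A fold against a group in which no library lists the gene is a lower bound, computed with 9 counts per library in that group.

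The 34 gene lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The lists cover early germ cell, later germ cell and meiosis, naive, core and formative pluripotency, mesoderm, endoderm, neuroectoderm, trophoblast, Hox, stromal, blood and endothelial, oestrogen-responsive, BPA receptor, aryl hydrocarbon receptor, Nrf2, integrated stress, p53, hypoxia and glycolysis, cholesterol, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, DNA replication, mitosis, DNA methylation, H3K9 and H3K27 methylation, imprinted, BMP, Wnt, Nodal, FGF, immediate early and histone genes. Lists with at least 5 tested genes were tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists; camera with an estimated correlation and fry were run beside it. Named were the 6 largest fitted rises and 6 largest fitted falls among called genes with a mean of at least 1 CPM and no overlap between groups, gene models and pseudogenes passed over (or the 5 smallest p where none was called), up to 4 called members per list, or the member with the smallest p, Prdm1, Dppa3, Esr1, Esr2, Esrrg and Xist. List medians with unlisted genes at their bound equalled the plain medians in EpiLCs and PGCLCs under BPA, and are printed beside the plain median where they differ in the others. Genes outside this rule are said to be chosen later. The no-overlap condition was not applied to the interaction. There, the 6 largest fitted rises and the 2 largest fitted falls had a group in which no library listed the gene and are not named.

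Alternatives were RLE factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, limma-trend on the deposited CPM plus 1, replicate number as a block, a test against a 1.2-fold change, ribosomal protein genes left out, 1 fit of all 12 libraries, a fit of the 6 untreated libraries, and each library left out in turn. Added after seeing the data were unlisted genes counted as 9, genes listed in every library alone, loess offsets for GC content and length, and chromosomes 8 and X left out.

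The pipeline was tested on simulated data with 200 genes changed per comparison, drawn from the libraries' own levels and spread. Genes were drawn independently and no library was set apart, so the rates below may not hold where real libraries differ as a whole. In EpiLCs under BPA edgeR found 5.97%, 43.3% and 90.9% of 1.5-, 2- and 4-fold changes (4.12% of calls false), and in PGCLCs 29.9%, 61.2% and 92.4% (1.61% false). It found 14.9%, 62.7% and 86.4% for the stage difference (3.54% false) and 0%, 20.9% and 80.3% for the interaction (4.29% false). DESeq2 gave 33.0% to 45.7% false calls and limma voom 1.52% to 5.61%. A planted list of 30 genes had a camera p of at most 9.33e-28 and an unchanged list of at least 0.148 in all 4 comparisons. With independent genes this does not check camera on lists whose genes move together. The ribosomal protein list in EpiLCs, for 1, had an estimated correlation of 0.905. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9) joined the files and drew the figures.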

Results

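The data were gene counts from 12 mRNA libraries of mouse epiblast-like cells (EpiLCs) and primordial germ cell-like cells (PGCLCs), derived from embryonic stem cells that carry fluorescent reporters of Prdm1 (Blimp1) and Dppa3 (Stella). There were 4 groups of 3 libraries: untreated EpiLCs, EpiLCs exposed to 100 nM bisphenol A (BPA), untreated PGCLCs and PGCLCs of the BPA arm, the PGCLCs sorted for both reporters. The question was whether BPA changed the transcriptome of EpiLCs and of the PGCLCs made from them. Counts assigned to genes, in replicates 1, 2 and 3, were 21840315, 21425667 and 15367922 in untreated EpiLCs and 17717656, 11785338 and 22029195 in BPA EpiLCs. They were 31688679, 32047046 and 31747975 in untreated PGCLCs and 31493062, 30375633 and 34309195 in BPA PGCLCs. Each count file listed 14323 to 17468 genes, none with fewer than 10 counts. An unlisted gene is read here as 9 counts or fewer, which is 0.262 to 0.764 counts-per-million (CPM). The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries. Levels are mean ± SD in CPM and log2 changes are ± SE, with n = 3 per group. The SE is the absolute log2 change divided by the square root of the quasi-likelihood F. It thus rests on a spread moderated over all genes, with unlisted genes as 0.

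Untreated PGCLCs had higher levels of early germ cell and naive pluripotency transcripts than untreated EpiLCs. Prdm1, a repressor needed for germ cell specification (chromosome 10, 44437177 to 44528501, mm10), went from 10.5 ± 0.668 to 191 ± 11.3 CPM. Dppa3, an early germ cell marker (chromosome 6, 122626410 to 122630272), went from 17.2 ± 3.70 to 234 ± 24.3 CPM. Prdm14, which restores naive pluripotency in germ cells, was unlisted in every untreated EpiLC library and at least 147-fold higher in PGCLCs. Tfap2c was higher by 5.55 ± 0.11 and Ifitm1 by 5.26 ± 0.23 on the log2 scale, and all 11 early germ cell genes were higher (camera adjusted p = 2.23e-07, and adjusted p = 0.0629 with an estimated correlation). Of 13 naive pluripotency genes, 12 were higher, Esrrb by 5.74 ± 0.13, Nanog by 4.78 ± 0.15, Tdh by 3.90 ± 0.12 and Fbxo15 by 3.05 ± 0.09 (adjusted p = 2.23e-07). This was the 1 list of the stage comparison still called with an estimated correlation (adjusted p = 0.0120). Adjusted over the list alone, higher and lower genes numbered 11 and 0 (early germ cell), 12 and 1 (naive).

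Members of the endoderm, trophoblast, blood and endothelial, BMP, immediate early and H3K9 and H3K27 lists were also higher in PGCLCs. All 13 endoderm genes were higher, among them the endocytic receptor gene Cubn (10.74 ± 0.68; 1 EpiLC library did not list it), the laminin gene Lama1 (5.16 ± 0.36) and Dab2 (4.12 ± 0.39), with Afp at least 69.4-fold higher (list median 6.30, or 4.12 with unlisted genes at their bound). Camera gave the list an adjusted p of 1.42e-06, and adjusted p = 0.214 with an estimated correlation. All 11 BMP targets were higher, including Id1 (6.25 ± 0.25) and Id3 (4.57 ± 0.20). The list had adjusted p = 1.42e-06, and adjusted p = 0.0516 with an estimated correlation. Trophoblast genes were higher in 6 of 8 cases, such as Gata2 (4.71 ± 0.16) and Krt7 (2.81 ± 0.28), with median 3.76, or 1.74 at the bound. As a list they had adjusted p = 0.00833, and adjusted p = 0.179 with an estimated correlation. Blood and endothelial markers were higher in 7 of 8 cases, with Cdh5 at least 45.5-fold higher and median 5.67, or 2.12 at the bound. For the list, adjusted p = 0.00229, and adjusted p = 0.0698 with an estimated correlation. Jun (3.52 ± 0.20) and Fos (3.35 ± 0.24) were among 11 higher immediate early and dissociation-stress genes, against 3 lower, with median 1.28, or 0.93 at the bound. With the preset correlation adjusted p = 0.0397, and adjusted p = 0.509 with an estimated correlation. The H3K9 and H3K27 list holds both methylation and demethylation genes. Of its genes 10 were higher, with both kinds among them, and 1 was lower. Camera gave the list an adjusted p of 0.0123, and adjusted p = 0.428 with an estimated correlation. Higher and lower genes adjusted over the list alone numbered 13 and 0 (endoderm), 11 and 0 (BMP), 6 and 0 (trophoblast), 7 and 0 (blood and endothelial), 12 and 3 (immediate early), 10 and 1 (H3K9 and H3K27).

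Members of the formative, cholesterol, Nrf2, replication, Hox, Nodal, oxidative phosphorylation and ribosomal protein lists were lower in PGCLCs. The de novo DNA methyltransferases Dnmt3a (-2.97 ± 0.12) and Dnmt3b (-1.73 ± 0.12) and the Wnt effector Lef1 (-1.41 ± 0.12) were among 10 lower formative and primed epiblast genes, while Otx2 (2.75 ± 0.15) was 1 of 2 higher. The list had adjusted p = 0.00649, and adjusted p = 0.0698 with an estimated correlation. Of 24 cholesterol synthesis genes 23 were lower, such as Dhcr7 (-2.41 ± 0.10) and Msmo1 (-2.73 ± 0.12), with adjusted p = 2.65e-10, and adjusted p = 0.0629 with an estimated correlation. Targets of the oxidative stress factor Nrf2 were lower in 13 of 15 cases, such as the quinone reductase gene Nqo1 (-2.67 ± 0.15) and the cystine transporter gene Slc7a11 (-2.87 ± 0.24). As a list they had adjusted p = 3.49e-06, and adjusted p = 0.0749 with an estimated correlation. Lower DNA replication genes numbered 16 of 22, such as Gins2 (-2.62 ± 0.15) and Ccne1 (-1.83 ± 0.12). For the list, adjusted p = 1.55e-05, and adjusted p = 0.179 with an estimated correlation. Hox genes were lower in 11 cases and higher in 3, with Hoxb4 at -2.38 ± 0.30 and Hoxa4 at least 16.4-fold lower. With the preset correlation adjusted p = 0.0205, and adjusted p = 0.102 with an estimated correlation. The Nodal antagonist gene Lefty1 (-4.13 ± 0.21) was 1 of 6 lower Nodal targets. Camera gave the list an adjusted p of 0.0401, and adjusted p = 0.367 with an estimated correlation. Of the oxidative phosphorylation genes 52 were lower and 4 higher, and of the cytosolic ribosomal protein genes 61 lower and 3 higher. Their adjusted p were 1.36e-05 and 1.57e-07, and adjusted p = 0.660 and 0.622 with an estimated correlation. By adjustment over the list alone, higher and lower genes numbered 2 and 10 (formative), 1 and 23 (cholesterol), 0 and 13 (Nrf2), 0 and 18 (replication), 3 and 11 (Hox), 1 and 6 (Nodal), 4 and 54 (oxidative phosphorylation), 3 and 63 (ribosomal protein). Ribosomal protein and histone genes share sequence with other gene copies, so their values are uncertain.

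Over all genes, 9787 of 17608 differed between the stages (5348 higher and 4439 lower in PGCLCs; 3261 and 2396 by at least 2-fold), and 840 of these are pseudogenes or have most of their sequence shared with another gene. EpiLC and PGCLC libraries carry different naming schemes in the labels, so library batch and stage cannot be told apart. The fixed rule ranks genes by fitted change, which put first genes that no library of 1 stage listed, although measured changes such as that of Cubn exceed their bounds. Besides Prdm14 and Afp, the rises it names were in the proteoglycan gene Srgn, Nxf7 and the peptide transporter gene Slc15a1 (at least 94.7-, 75.3- and 65.0-fold) and in the ribosomal RNA gene n-R5-8s1 (at least 134-fold, uncertain because its copies share reads). The falls it names were in Zscan4e, the lipid transporter gene Mfsd2a, Usp17le, Usp17lb, the calcium sensor gene Hpca and the potassium channel subunit gene Abcc8 (at least 69.4-, 55.1-, 39.1-, 28.6-, 27.2- and 25.8-fold), of which Zscan4e, Usp17le and Usp17lb belong to families of near-identical copies. Outside the called lists, Sox2 (3.78 ± 0.12) and Sall4 (2.69 ± 0.10) were higher and Lin28a (-1.15 ± 0.09) and the neural gene Sox1 (-3.38 ± 0.19) lower. The mesoderm genes Hand1 (9.05 ± 0.60) and Kdr (5.42 ± 0.51), which 2 and 1 untreated EpiLC libraries did not list, the collagen gene Col1a1 (5.80 ± 0.22), Tet2 (3.09 ± 0.30) and the imprinted genes Igf2 (6.70 ± 0.17) and H19 (7.12 ± 0.22) were higher. The receptor gene Esrrg was at least 1.64-fold higher and Esr2 at least 1.75-fold lower, with Esr1 under the filter and not tested. Xist, the RNA of X inactivation, was higher (1.71 ± 0.40). Of 26 later germ cell and meiosis genes 11 were higher and 6 lower, over all genes and over the list alone (adjusted p = 0.489). The 17 lists not called, this one included, had adjusted p between 0.055 and 0.925. The median, mean and test differed in sign for neuroectoderm (median -0.37, mean 0.49, test down; median 0.02 at the bound), aryl hydrocarbon receptor (-0.39, 0.10, down), integrated stress (0.26, -0.12, down), DNA methylation (0.06, -0.04, down) and Wnt (0.32, 1.80, down) lists.

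In EpiLCs no gene passed the test for a BPA effect. The 5 genes with the smallest p included the nuclear RNA Neat1 (20.8 ± 0.711 to 14.9 ± 1.10 CPM from untreated to BPA), the glucuronyltransferase gene B3gat1 (1.59 ± 0.168 to 2.72 ± 0.114 CPM) and the repressor gene Zbtb7a (10.5 ± 0.956 to 14.7 ± 1.30 CPM). The others were unlisted in every BPA library: the fructose bisphosphatase gene Fbp2 (0.987 ± 0.329 CPM in untreated libraries, at least 1.78-fold lower) and Dppa5c (4.40 ± 2.16 CPM, at least 7.92-fold lower), a pseudogene that shares reads with its relatives and is uncertain. All had adjusted p = 0.943. The reporter genes had log2 changes of 0.13 ± 0.12 (Prdm1) and -0.07 ± 0.18 (Dppa3), and the oestrogen receptor gene Esr2 of 0.86 ± 1.01. By edgeR 0 of 15252 genes passed, and 118 had an unadjusted p under 0.05, against 762.6 expected with no effect. DESeq2 called 16 (4 higher, 12 lower), and limma voom and limma-trend 0. On counts simulated from these libraries' levels and spread, edgeR found 5.97% of 1.5-fold, 43.3% of 2-fold and 90.9% of 4-fold changes. The simulation held no library that stands apart, as untreated replicate 3 does here, so these shares may not hold for the real libraries.

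Of 32 gene lists tested in EpiLCs, 5 passed camera with its preset correlation. The oxidative phosphorylation list was called lower in BPA (median -0.28, 2 of 81 positive, 0 passing; adjusted p = 2.94e-07, and adjusted p = 0.881 with an estimated correlation), with the cytochrome c oxidase gene Cox7a1 at -0.55 ± 0.28. So was the cytosolic ribosomal protein list (median -0.27, 3 of 88 positive, 0 passing; adjusted p = 2.20e-07, and adjusted p = 0.881 with an estimated correlation), with Rpl23a at -0.30 ± 0.15. The replication-dependent histone list (median -0.33, 2 of 20 positive, 0 passing; adjusted p = 0.0120, and adjusted p = 0.881 with an estimated correlation) and the hypoxia and glycolysis list (median -0.15, 7 of 25 positive, 0 passing; adjusted p = 0.0120, and adjusted p = 0.881 with an estimated correlation) were also called lower, with Ndrg1 at -0.72 ± 0.28. The list of targets of the tumour suppressor p53 was called higher (median 0.14, 12 of 16 positive, 0 passing; adjusted p = 0.0300, and adjusted p = 0.881 with an estimated correlation), with the kinase gene Plk2 at 0.36 ± 0.14 (adjusted p = 0.943). None passed with fry. Core pluripotency genes were not called (7 of 11 positive, median 0.06, camera adjusted p = 0.743), although Pou5f1, the member with the smallest p, was at -0.24 ± 0.16. The lists not called, this one included, had camera adjusted p between 0.0978 and 0.949. When adjusted over the list alone, 0 members of any list passed.

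Untreated EpiLC replicate 3 stood apart from the other libraries of its stage: ribosomal protein genes took 14.4% of its counts against 8.41% to 9.49% elsewhere, and it lay at -93.7 on the first principal component against 9.02 to 27.6. Without it, the oxidative phosphorylation and ribosomal protein lists turned to higher in BPA (adjusted p = 0.00313 and 0.00082), the histone list turned and did not pass (adjusted p = 0.844) and the hypoxia list did not pass (adjusted p = 0.075). The p53 list still passed (adjusted p = 0.0206), and 4 lists were called higher and 0 lower. However, 0 lists were called higher without untreated replicate 1 or 2, without BPA replicate 2 or 3, or with the replicate block. The p53 list lost its call in each of these settings. The number of lists called was 2 without untreated replicate 1, 2 without BPA replicate 2 and 3 without BPA replicate 3. Dppa3 had a log2 change of 0.10 without untreated replicate 3 and of 0.03 without BPA replicate 2. For 5 lists the median, mean and test differed in sign: meiosis (0.02, -0.01, test down), naive pluripotency (-0.02, 0.04, down), endoderm (-0.04, -0.04, up), Wnt (0.03, -0.11, up) and FGF (0.05, 0.04, down). The blood and endothelial list had only 4 measured genes in EpiLCs and was not tested there.

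In PGCLCs of the BPA arm, part of the endoderm list rose. Afp, the fetal plasma protein alpha-fetoprotein (chromosome 5, 90490737 to 90508907), went from 33.1 ± 11.4 to 2132 ± 673 CPM, a log2 change of 6.01 ± 0.35. Ttr, the thyroxine carrier transthyretin (chromosome 18, 20665280 to 20674321), went from 8.87 ± 1.43 to 375 ± 111 CPM (5.40 ± 0.26). The apolipoprotein gene Apoa1 rose by 5.35 ± 0.39 and the endoderm transcription factor gene Foxa2 by 2.83 ± 0.42. Of 13 endoderm genes 6 rose and 0 fell (7 and 0 when adjusted over the list alone), with a list median of 1.46 (camera adjusted p = 0.00182, and adjusted p = 0.547 with an estimated correlation). Gata4, Gata6, Sox17, Sox7, Hhex, Cubn and Lama1 (-0.45) did not pass. The levels differed between BPA libraries, with Apoa1 at 1153, 1134 and 443 CPM and Foxa2 at 31.1, 29.4 and 10.4 CPM in replicates 1, 2 and 3.

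Members of the early germ cell and pluripotency lists fell in BPA PGCLCs. The germ cell regulators Prdm14 (-0.63 ± 0.09), Tfap2c (-0.41 ± 0.08) and Prdm1 (-0.32 ± 0.08; 190.0 ± 11.1 to 152 ± 12.1 CPM) and the membrane protein gene Ifitm3 (-0.65 ± 0.12) fell, and the other reporter gene Dppa3 had a change of -0.09 ± 0.10 that did not pass (adjusted p = 0.670). These were the 4 of 11 early germ cell genes that fell (6 when adjusted over the list alone; median -0.32, adjusted p = 0.00801, and adjusted p = 0.430 with an estimated correlation). Among naive pluripotency genes 6 of 13 fell (8 over the list alone), such as Esrrb (-0.39 ± 0.05), the X-linked Nr0b1 (-1.01 ± 0.16) and Nanog (-0.28 ± 0.06), with adjusted p = 0.00340, and adjusted p = 0.283 with an estimated correlation. Among core pluripotency genes 5 of 11 fell (8 down and 1 up over the list alone), with Pou5f1 (chromosome 17, 35506018 to 35510772) from 443 ± 20.8 to 294 ± 13.1 CPM and Tdgf1 at -0.58 ± 0.11. The list had adjusted p = 0.00291, and adjusted p = 0.283 with an estimated correlation. The Nodal antagonist genes Lefty2 (-0.75 ± 0.08) and Lefty1 (-0.74 ± 0.11) fell with Tdgf1 and Smad7 (-0.41 ± 0.11), 4 of 7 Nodal targets in all and over the list alone. As a list they had adjusted p = 0.0130, and adjusted p = 0.345 with an estimated correlation.

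Members of the Nrf2, cholesterol synthesis and imprinted lists rose in BPA PGCLCs. The peroxiredoxin reductase gene Srxn1 (chromosome 2, 152105516 to 152111376) went from 24.1 ± 2.42 to 95.3 ± 19.9 CPM, with Osgin1 at 4.94 ± 0.57 (24.2, 22.0 and 7.21 CPM in BPA replicates 1, 2 and 3) and Nqo1 at 1.39 ± 0.17, both on chromosome 8. In all, 5 of 15 Nrf2 targets rose and 0 fell (10 and 1 over the list alone). For the list, adjusted p = 0.00182, and adjusted p = 0.418 with an estimated correlation. The sterol oxidase gene Msmo1 (0.73 ± 0.12; chromosome 8) and the last-step reductase gene Dhcr7 (0.46 ± 0.10) were among 6 of 24 cholesterol synthesis genes that rose (10 up and 1 down over the list alone). With the preset correlation adjusted p = 0.00220, and adjusted p = 0.540 with an estimated correlation. The cholesterol list did not pass fry (adjusted p = 0.0846). Of 27 imprinted genes 12 rose and 2 fell (14 and 4 over the list alone; median 0.52). The growth factor gene Igf2 (chromosome 7, 142650766 to 142666816) went from 292 ± 40.6 to 821 ± 34.9 CPM, and Peg10 rose by 1.59 ± 0.11 and the maternally expressed RNAs Rian by 1.95 ± 0.19 and Meg3 by 2.42 ± 0.25. Camera gave the list an adjusted p of 0.00768, and adjusted p = 0.302 with an estimated correlation. H19, chosen after its values were seen as the neighbour of Igf2, rose by 1.32 ± 0.16.

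Members of the ribosomal protein, respiration and cell cycle lists fell. Cytosolic ribosomal protein genes fell in 68 of 88 cases and rose in 1 (73 and 1 over the list alone), with Rpl21 at -1.02 ± 0.05, Rps29 at -1.17 ± 0.07 and a median of -0.41 (adjusted p = 1.45e-25, and adjusted p = 0.345 with an estimated correlation). Their share of counts was 6.24% to 6.63% in untreated and 4.86% to 5.02% in BPA libraries. The oxidative phosphorylation genes Atp5g3 (-0.61 ± 0.05) and Cox6c (-0.72 ± 0.07) were 2 of 37 that fell among 80, with 0 rising (48 down over the list alone). The list had adjusted p = 5.59e-15, and adjusted p = 0.283 with an estimated correlation. Mitosis genes fell in 6 of 21 cases (9 over the list alone), such as Ube2c (-0.51 ± 0.06), Top2a (-0.32 ± 0.04) and Cdk1 (-0.40 ± 0.06), with adjusted p = 0.000221, and adjusted p = 0.302 with an estimated correlation. DNA replication genes fell in 3 of 22 cases (4 over the list alone), including Rrm2 (-0.56 ± 0.08) and Pcna (-0.34 ± 0.06), with adjusted p = 0.00340, and adjusted p = 0.430 with an estimated correlation. Replication-dependent histone genes had a median of -1.46 with 3 of 42 down, such as Hist1h3e (-2.48 ± 0.42) and Hist1h3c (-1.26 ± 0.32), and H1f0, a linker histone gene expressed outside replication, up (1.13 ± 0.21; 1 down and 1 up over the list alone). As a list they had adjusted p = 0.000711, and adjusted p = 0.283 with an estimated correlation. Ribosomal protein and histone genes share reads with other copies, and most histone transcripts lack a poly(A) tail, so these values are uncertain. The calls of these lists were not examined with the GC and length offsets.

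Lists linked to BPA itself did not pass camera as groups, but the oestrogen-responsive list passed fry. Of 15 oestrogen-responsive genes Igfbp4 (1.27 ± 0.12), Pdzk1 (1.52 ± 0.26), Ctsd (0.56 ± 0.12) and Ltf (at least 8.65-fold) rose and 0 fell (6 and 2 over the list alone). This list had camera adjusted p = 0.0959, and 0.345 with an estimated correlation. Its fry adjusted p was 0.00624 (direction up). The oestrogen receptor genes Esr1 and Esr2 were not among the genes tested in PGCLCs under BPA. None of the 7 tested receptor genes proposed to bind BPA passed (list adjusted p = 0.630), with Esrrg at 1.16 ± 0.65 and the glucocorticoid receptor gene Nr3c1 at -0.63 ± 0.18 (adjusted p = 0.300 and 0.0568). The aryl hydrocarbon receptor targets Cyp1a1 (1.19 ± 0.24) and Cyp1b1 (-0.84 ± 0.16) went opposite ways (list adjusted p = 0.892). Adjusted over the list alone, 0 and 0 (receptors), 2 and 1 (aryl hydrocarbon receptor targets) rose and fell.

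Other lists had members that changed without a camera call for the list, given here with the list's camera adjusted p last in each bracket. Among them the Wnt list passed fry (up, adjusted p = 0.0167). Among p53 targets 5 of 16 fell, with the X-linked Eda2r at -0.85 ± 0.10 and the apoptosis gene Pmaip1 at -0.73 ± 0.10 (6 down and 1 up over the list alone; 0.140). Integrated stress genes rose in 4 of 17 cases, such as the serine synthesis genes Psat1 at 0.34 ± 0.05 and Phgdh at 0.64 ± 0.12 (4 up and 1 down over the list alone; 0.569). FGF and ERK targets rose in 3 cases, with Phlda1 at 1.88 ± 0.25, and fell in 4, with Spry4 at -0.70 ± 0.11 and Spry2 at -0.50 ± 0.09 (4 and 5 over the list alone; 0.547). Dnmt3a rose (0.53 ± 0.11) and Tet1 fell (-0.30 ± 0.07) among 16 DNA methylation genes (1 up and 4 down over the list alone; 0.410). Ezh1 rose (0.44 ± 0.12) and Jarid2 fell (-0.27 ± 0.05) among 18 H3K9 and H3K27 methylation genes (4 up and 3 down over the list alone; 0.865). The Wnt targets Tcf7 (0.42 ± 0.08) and Lef1 (0.56 ± 0.13) rose (0.268), as did the BMP pathway gene Smad9 (1.75 ± 0.33; BMP targets 0.994), and the formative gene Tcf15 fell (-0.79 ± 0.15; 0.994). Atf3 (2.56 ± 0.39; 30.2, 31.0 and 11.8 CPM in BPA replicates 1, 2 and 3) and Egr1 (0.89 ± 0.18) rose and the chaperone gene Hsph1 fell (-0.34 ± 0.08) among 20 immediate early and dissociation-stress genes (5 up and 1 down over the list alone; 0.630). Pfkfb4 rose (1.00 ± 0.24) among 25 hypoxia and glycolysis genes (0.547). Over the list alone, rises and falls numbered 2 and 0 (Wnt), 1 and 1 (BMP), 2 and 1 (formative), 0 and 0 (hypoxia).

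Markers of further cell types changed in single genes, again with the list's camera adjusted p last. By fry the neuroectoderm, blood and endothelial, and later germ cell lists passed as lower (adjusted p = 0.0127, 0.0244 and 0.0345). The streak genes Lhx1 (3.13 ± 0.79) and Mixl1 (5.58 ± 1.45; 2 untreated libraries did not list it) were called higher from BPA replicates 1 and 2 alone, at 44.9 and 42.5 CPM for Lhx1 and 14.8 and 15.3 CPM for Mixl1. In BPA replicate 3 they lay at 3.51 and 0.589 CPM, within the untreated range (up to 3.92 and 0.632 CPM). Kdr (-0.95 ± 0.26) and Evx1 (-1.03 ± 0.28) fell (mesoderm list 0.994). The trophoblast gene Cdx2 rose (1.71 ± 0.42) and Krt7 fell (-0.85 ± 0.21; 0.793), and Tubb3, on chromosome 8, fell (-0.51 ± 0.11; neuroectoderm 0.120). Hoxa11 was at least 2.52-fold lower (Hox 0.793), and Fbln1 was called higher (0.69 ± 0.19; fibroblast and stromal 0.553) from BPA replicates 1 and 2 (74.4 and 70.2 CPM), with replicate 3 at 45.7 CPM against up to 45.1 CPM in untreated libraries. The endothelial receptor gene Tek fell (-1.32 ± 0.28) and the embryonic globin gene Hbb-bh1 was at least 5.79-fold higher (blood and endothelial 0.320). That bound rests on BPA replicate 3 (4.18 CPM), as Hbb-bh1 was at 0.326 and 0.402 CPM in replicates 1 and 2, near the listing limit. Among 27 later germ cell and meiosis genes, Stag3 (0.68 ± 0.13) and Rec8 (0.55 ± 0.13) rose and Sohlh2 fell (-0.61 ± 0.11; 0.148). Rises and falls over the list alone numbered 3 and 2 (mesoderm), 1 and 2 (trophoblast), 0 and 1 (neuroectoderm), 0 and 0 (Hox), 0 and 0 (stromal), 1 and 3 (blood and endothelial), 3 and 3 (later germ cell). Median, mean and test differed in sign for trophoblast (-0.01, 0.11, test down), BMP (0.05, 0.11, down), H3K9 and H3K27 (0.01, 0.05, down) and FGF (-0.13, 0.17, down) lists.

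In all, 2321 of 16753 genes differed between BPA and untreated PGCLCs, 1362 higher and 959 lower (58.7% higher), 606 and 180 of them by at least 2-fold. The fixed rule ranks genes by fitted change, which for rises put first genes that no untreated library listed, although measured rises such as that of Afp exceed their bounds: Card14, Eps8l3, Trf (transferrin), Sec16b, Pde6c and Itih2, at least 40.8-, 30.8-, 25.4-, 15.2-, 14.2- and 13.9-fold. The largest falls by that rule were in n-R5-8s1 (-3.60 ± 0.24), Xlr3c (-3.28 ± 0.89), the lipoxygenase gene Alox15 (-2.60 ± 0.51), Hist1h3e, the small RNA gene Scarna2 (-2.41 ± 0.57) and Xist (-2.37 ± 0.21; chromosome X, 103460366 to 103483254; 23.5 ± 1.27 to 4.52 ± 1.21 CPM). The rule took only genes in which every BPA library lay on 1 side of every untreated library. The separation of these 12 genes was thus fixed by the choice and is no further support for them. Of the 12, n-R5-8s1, Xlr3c and Hist1h3e share reads with other copies. The number of genes called was 1243, 1110 and 891 without untreated replicate 1, 2 and 3 and 677, 668 and 3206 without BPA replicate 1, 2 and 3, and it was 863 when tested against a 1.2-fold change. With offsets for GC content and length, an alternative added after the data were seen, 1057 genes were higher and 1336 lower (44.2% higher), and 38 of the 91 called genes named here kept their call under every setting. The BPA and untreated PGCLC libraries carry different naming schemes in the labels, so library batch and treatment cannot be told apart, and whether the PGCLC medium held BPA is not stated.

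**Figure D1:**
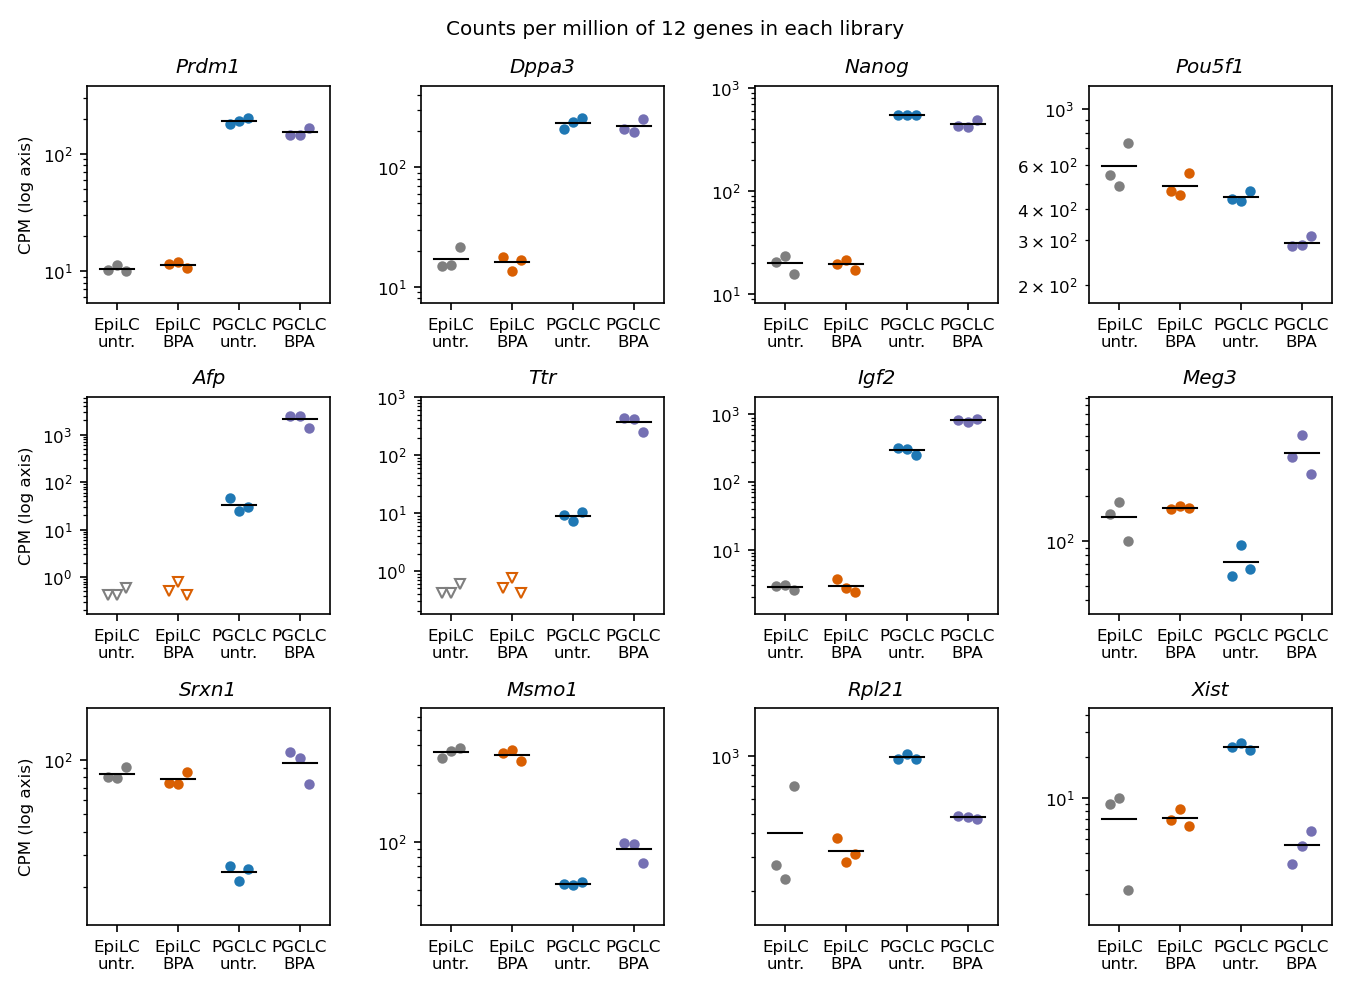
CPM of 12 genes on a log axis in each of the 12 libraries, 3 points per group, with the group mean as a black line. Hollow triangles mark libraries that do not list the gene, drawn at 9 counts; "untr." is untreated, and Ttr goes from 8.87 ± 1.43 to 375 ± 111 CPM and Xist from 23.5 ± 1.27 to 4.52 ± 1.21 CPM between untreated and BPA PGCLCs.

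**Figure D2:**
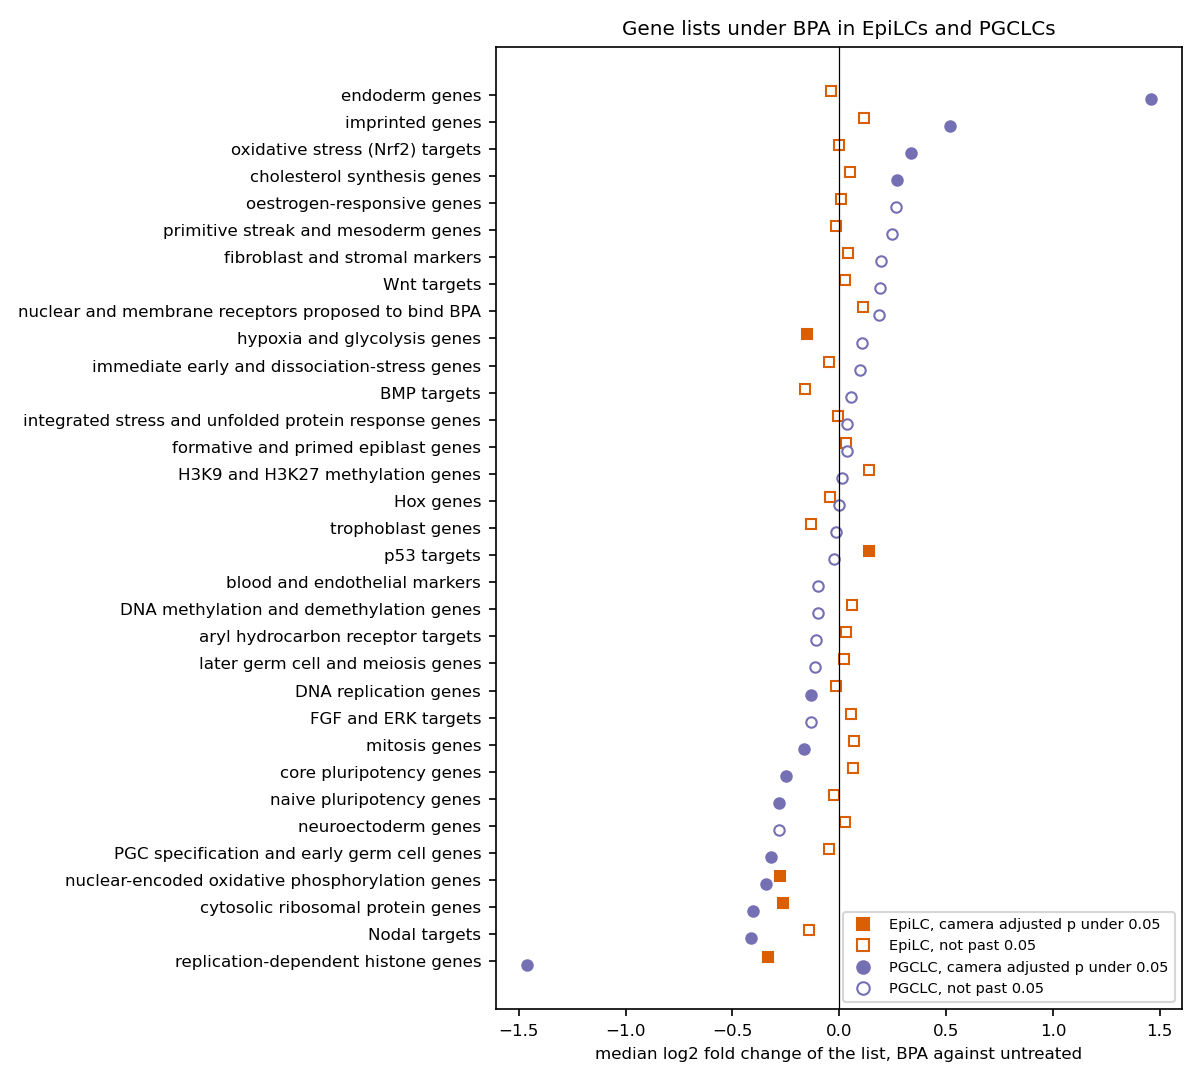
Median log2 change under BPA of each fixed gene list in EpiLCs (orange squares) and PGCLCs (purple circles), 3 libraries per group; filled symbols passed camera at an adjusted p under 0.05 with the preset correlation, and none passed with an estimated one. The PGCLC medians run from -1.46 (histone genes) to 1.46 (endoderm genes).

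By chromosome, a feature examined only after the data were seen, genes of chromosome 8 and of the X moved as sets in BPA PGCLCs. The median log2 change was 0.17 over 593 protein-coding genes of chromosome 8 (74.5% positive) and -0.27 over 371 of the X (25.6% positive), and lay between -0.05 and 0.03 on the other 18 chromosomes. Against the mean of all 6 PGCLC libraries, the chromosome 8 median was -0.10 to -0.07 in untreated and 0.07 to 0.09 in BPA libraries, and that of the X was 0.09 to 0.19 and -0.13 to -0.10. In EpiLCs the medians were -0.011 (chromosome 8) and 0.071 (X), and -0.004 and -0.006 without untreated replicate 3. Of the genes named under BPA, Osgin1, Nqo1, Msmo1 and Tubb3 lie on chromosome 8 and Xlr3c, Xlr3a, Xist, Nr0b1, Eda2r and Efhc2 on the X. With genes of both chromosomes left out, 1958 genes were called.

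**Figure D3:**
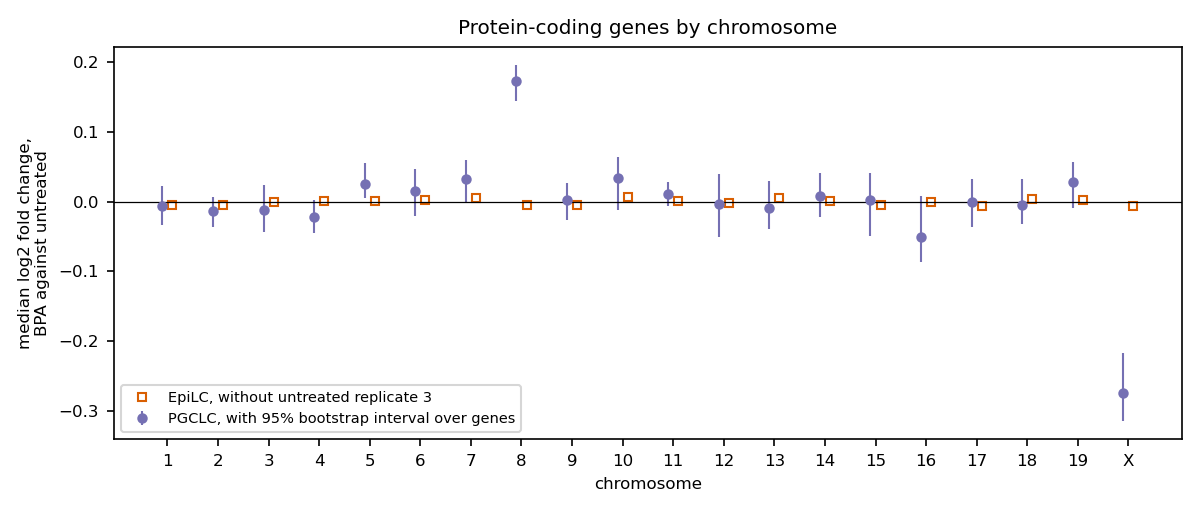
Median log2 change (BPA against untreated) of protein-coding genes on each chromosome in PGCLCs (purple, with a 95% bootstrap interval over genes) and in EpiLCs without untreated replicate 3 (orange squares). Chromosome 8 lay at 0.17 and the X at -0.27 in PGCLCs.

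The difference between BPA and untreated libraries itself differed between PGCLCs and EpiLCs for 232 of 17608 genes, being more positive in PGCLCs for 177 and more negative for 55. Its PGCLC part holds library batch as well as treatment, which cannot be told apart there. More positive were the Nrf2 targets Srxn1 (2.07 ± 0.21), Nqo1 (1.43 ± 0.20) and Osgin1 (4.85 ± 0.70) and the imprinted genes Igf2 (1.43 ± 0.22), H19 (1.61 ± 0.25), Meg3 (2.20 ± 0.36) and Rian (1.69 ± 0.29). So were the oestrogen-responsive Igfbp4 (1.34 ± 0.22), the cholesterol synthesis gene Msmo1 (0.76 ± 0.16) and the stress factor gene Atf3 (2.60 ± 0.45). More negative were Alox15 (-2.66 ± 0.37), Efhc2 (-2.27 ± 0.29), Pmaip1 (-0.92 ± 0.16), Rrm2 (-0.64 ± 0.12), Xlr3a (-1.86 ± 0.21) and Lars2 (-2.02 ± 0.35), of which Efhc2 and Xlr3a are X-linked and Lars2 and Xlr3a share reads with other sequence. Xist (-2.36 ± 0.56) did not pass (adjusted p = 0.0733). The count was 119 without untreated EpiLC replicate 1, 767 without untreated EpiLC replicate 3, 83, 113 and 117 without BPA EpiLC replicates 1, 2 and 3, and 120, 117 and 744 without BPA PGCLC replicates 1, 2 and 3. Of 33 lists 13 passed camera. Endoderm (median 1.21, or 1.31 with unlisted genes at their bound), Nrf2, cholesterol and imprinted genes (0.42, or 0.24) were more positive in PGCLCs. Early germ cell, naive and core pluripotency, blood and endothelial (-0.41, or -0.51), p53, oxidative phosphorylation, ribosomal protein, replication and mitosis genes were more negative. Of 13 endoderm genes 5, and of 8 blood and endothelial genes 4, had a group in which no library listed them. Only 6 endoderm and 4 blood and endothelial genes were tested in EpiLCs, so these 2 differences rest largely on the PGCLC change. None of the 13 lists passed with an estimated correlation (adjusted p = 0.193 to 0.761), and the 20 others had adjusted p from 0.0517 to 0.921 with the preset one. By fry 8 of the 13 passed. Of the 20 others, the oestrogen-responsive (up, adjusted p = 8.00e-05) and neuroectoderm (down, adjusted p = 0.00363) lists passed fry. More positive and more negative genes adjusted over the list alone numbered 10 and 2 (imprinted, against 6 and 0 over all genes), 3 and 0 (Nrf2), 1 and 0 (cholesterol), 0 and 2 (naive), 0 and 3 (p53) and 0 and 1 each for early germ cell, core, blood and endothelial and replication genes, with 0 and 0 in the other 4 lists. Median, mean and test differed in sign for neuroectoderm (-0.18, 0.05, test down; median -0.32 at the bound), receptor (0.15, -0.02, down; -0.02 at the bound) and FGF (-0.28, 0.14, down) lists. Without untreated EpiLC replicate 2 the oxidative phosphorylation list turned to more positive and did not pass (adjusted p = 0.813). The number of lists was 6 and 4 without untreated EpiLC replicates 1 and 2 and 6 without BPA EpiLC replicate 3.

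Among 14308 genes tested in both cell types, 0 were called in both, with 0 called in EpiLCs and 1168 higher and 899 lower in PGCLCs. In EpiLCs, the 1168 genes that rose in PGCLCs had a median log2 change of 0.05 and the 899 that fell one of -0.11 (camera p = 0.417 and 0.428 with an estimated correlation); without untreated EpiLC replicate 3 the medians were -0.01 and 0.03.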

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

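The tests of endoderm cells, of a lower germ cell share, of an inactive X and of shared reads, the GC and length offsets and the chromosome sets were chosen only after the results were seen. The difference between BPA and untreated libraries differed between PGCLCs and EpiLCs for 232 genes by a test of the difference itself. In its PGCLC part library batch cannot be told apart from treatment. The log2 differences, PGCLC minus EpiLC, were 2.07 (Srxn1), 1.43 (Nqo1), 4.85 (Osgin1), 1.43 (Igf2), 1.61 (H19), 2.20 (Meg3), 1.69 (Rian), 1.34 (Igfbp4), 0.76 (Msmo1) and 2.60 (Atf3). They were -2.66 (Alox15), -2.27 (Efhc2), -2.02 (Lars2), -1.86 (Xlr3a), -0.92 (Pmaip1) and -0.64 (Rrm2) for genes with the more negative change in PGCLCs. Lists whose effect was higher in PGCLCs by camera were endoderm (adjusted p = 0.000968), Nrf2 (0.000638), cholesterol (0.0244) and imprinted genes (0.0395). Lower ones were early germ cell (0.0294), naive (0.0228) and core pluripotency (0.00506), blood and endothelial (0.0294), p53 (0.0294), oxidative phosphorylation (0.0473, turned to higher at 0.813 without untreated EpiLC replicate 2), ribosomal protein (0.00184), DNA replication (0.0228) and mitosis genes (0.00506). With an estimated correlation the adjusted p were 0.395, 0.249, 0.459 and 0.333 for the former and 0.379, 0.193, 0.193, 0.27, 0.293, 0.761, 0.684, 0.459 and 0.193 for the latter. Among the endoderm and the blood and endothelial genes, 5 of 13 and 4 of 8 had a group in which no library listed them.

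Of 100 splits drawn from the 200 that keep the stages apart, 8 gave as many genes as the real 232 and 7 as many lists as the real 13, the real one included, with 374 genes and 15 lists as the highest others. By this share chance is not excluded for the interaction counts, but the share is no measure of it. Of the splits drawn, 9 kept the real PGCLC groups and so carried their difference, among them every one that reached the counts, and the highest of the others had 14 genes. For the other comparisons 10 splits of 6 libraries are too few for a share under 0.05. As many EpiLC genes as the real 0 came from 10 of 10 splits, highest other 0, and as many lists as the real 5 from 2, highest other 5. In PGCLCs 1 split gave as many genes (real 2321, highest other 0) and 1 as many lists (real 13, highest other 10), and between stages 1 (real 9787, highest other 0) and 1 (real 16, highest other 12).

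Of 13 endoderm genes 6 were called higher and 0 lower in BPA PGCLCs, with median log2 change 1.46 (0.57 to 2.83). For the list, camera adjusted p = 0.547 with an estimated correlation, which was 0.83. Brackets after medians in this paragraph are 95% bootstrap intervals over genes. They do not measure the spread between libraries and treat correlated genes as independent. A lower germ cell share made up by many lineages would raise their markers too. Yet 52 markers of other cell types had a median of -0.050 (-0.14 to 0.29), with 9 higher and 9 lower by more than 2 SE. A lower share made up mainly by endoderm cells would leave these markers flat, so they cannot decide about it. GC content and length as the whole cause are argued against by a median of 1.21 with offsets, with 6 of 13 members still called. Library batches cannot be told apart from treatment, since 0 naming schemes hold both PGCLC groups, and a BPA effect or endoderm-like transcription in the sorted cells stays open as an untested hypothesis. RNA from endoderm cells, which the sort for both reporters was set to leave out, stays open too, with no profile of such cells measured: 9 of the 13 genes were higher and 0 lower by more than 2 SE, but of the 9 Gata4 (the median gene) and Cubn lay at untreated levels in BPA replicate 3 (43.9 and 459 CPM, against 35.9 to 50.7 and 460 to 754 CPM).

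Chromosome 8 was higher and the X lower in BPA PGCLCs. With GC and length offsets the chromosome 8 median went from 0.17 to 0.077, under 50% of it, and that of the X from -0.27 to -0.27, but the median of all genes also went from 0.006 to -0.067; against that median, 86.7% of the chromosome 8 shift and 71.7% of the X shift were left, which argues against GC content and length as the whole cause. More cells with an inactive X is argued against by Xist, which fell by 2.37 on the log2 scale. A changed copy number of both chromosomes in a share of cells would move every part of them: 16 of 16 bins of 20 Mb (100%) shifted the way of their chromosome, while 0 of the 18 other chromosomes had all bins on 1 side and 58 of their 123 bins were higher. Copy number may therefore account for it, as a hypothesis found and tested on the same data, and whether it came with BPA, with the passage of the cells or with the batch cannot be told from these libraries.

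Processed pseudogenes were lower in PGCLCs than in EpiLCs: of 208 with at least 5 CPM, 192 were lower (182 called), 8 were called higher and the median log2 difference was -3.97. Their share of counts was 1.08% to 1.46% in EpiLC and 0.215% to 0.284% in PGCLC libraries. Lower expression of their parents is argued against as the whole cause, since 39 parent genes had a median of -0.58 against -3.46 for their pseudogenes. Reads shared between copies and counted differently at the stages may be the source. The median of 120 protein-coding genes with most of their sequence shared lay -0.89 from that of 5702 with none shared. Ribosomal protein genes, whose list median between stages was -0.80, were not left out of this set. The difference therefore cannot tell shared reads from lower expression of such genes. The 95% bootstrap interval of this difference, over genes and not libraries, was -1.11 to -0.63. Of the 9787 genes called between stages, 840 are pseudogenes or have most of their sequence shared, and the cell stage itself stays open as an untested source.

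Reads that did not align uniquely have a summary row in 4 count files alone: BPA EpiLC replicate 2 (9.82% of all reads counted there) and BPA PGCLC replicates 1, 2 and 3 (0.455%, 0.459% and 0.522%). These are outside the gene counts and have no value in the other 8 files, which include all untreated PGCLC files. Whether reads were counted alike in both PGCLC groups is not known, which leaves the falls of genes with shared reads (ribosomal protein, histone and Xlr genes, n-R5-8s1 and Lars2) uncertain.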

How the results depend on the processing

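Unlisted genes as 9, genes listed in every library, GC and length offsets and chromosomes 8 and X left out were chosen after seeing the data. No gene was called in EpiLCs except 16 by DESeq2, and the overlap with PGCLCs was 0 in every setting run. For BPA in PGCLCs the other settings kept the count within 1.5 times of 2321 (1579 to 3462); a test against a 1.2-fold change gave 863, and 1 library left out 668 to 3206. With offsets 44.2% of calls were higher, against 58.7%. Between stages counts ran from 7870 to 10314, and 8687 to 9715 with 1 library left out; without a filter the median of all genes moved to 0.20 from 0.07, and changes are relative to it. The interaction count of 232 was 897 by DESeq2, 141 by limma voom, 94 with the replicate block, 519 with unlisted genes as 9, and 83 to 767 with 1 library left out. In all of these the cause was not tested. Number pairing was checked: libraries of the same number had correlations of 0.09, 0.01 and 0.04 (EpiLC) and 0.02, 0.01 and -0.03 (PGCLC), so the block is no pairing; with it 1618 genes were called in PGCLCs.

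Lists called were 0, 0, 1 and 0 (EpiLC, PGCLC, stage, interaction) with an estimated correlation, and 0, 17, 31 and 10 by fry, against 5, 13, 16 and 13. With 1 library left out they were 2 to 5, 12 to 14, 15 to 18 and 4 to 14. List calls were not examined under the alternatives added after seeing the data, GC and length offsets included. Nor were they examined with ribosomal protein genes left out, against a 1.2-fold change, or with DESeq2, limma voom or limma-trend. In EpiLCs the adjusted p ran from 3.04e-12 to 0.00313 (oxidative phosphorylation), 1.36e-12 to 0.00082 (ribosomal protein) and 0.00104 to 0.844 (histone), each highest without untreated replicate 3, where the direction turned; in the interaction that of oxidative phosphorylation ran from 5.03e-16 to 0.813, turned without untreated EpiLC replicate 2. Dppa3 in EpiLCs ran from -0.15 to 0.10 (0.03 without BPA replicate 2), and in PGCLCs it was 0.14 with offsets. The cause was not tested.

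Of the named genes called, 38 of 91 (PGCLC), 53 of 56 (stage) and 6 of 16 (interaction) kept their call in every setting, and none turned direction. Limma-trend on deposited CPM was not run for the stage or the interaction, since the tables were normalised separately. A smallest library of 11785338 counts and the limit of 10 listed counts leave genes near 0.764 CPM and below undecided.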

Other observations

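The gene families here were chosen after their values were seen, and their medians are of fitted changes with unlisted genes as 0. In BPA PGCLCs, 8 of 9 tested apolipoprotein genes of the A, B, C, E, H and M types rose (median log2 change 4.63). Among them Apob, which carries dietary and hepatic lipid, was at 4.55 ± 0.31. Other apolipoprotein types were not counted. Of 9 fibrinogen and serpin A genes, which encode secreted plasma proteins, 5 rose (median 4.61), with Fgb at 4.61 ± 0.21. Cubn and Gata4, of the endoderm list, had 0.76 ± 0.36 and 1.46 ± 0.42 and did not pass (adjusted p = 0.207 and 0.0559). Of 9 Xlr genes, an X-linked family of near-identical copies whose values are uncertain, 7 fell (median -2.17), with Xlr3a at -1.85 ± 0.16.

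A hypothesis set before the result was that genes changed in PGCLCs had already moved the same way in EpiLCs. In EpiLCs the 1168 genes that rose in PGCLCs had a camera p of 0.417 and the 899 that fell 0.428, both with an estimated correlation, so neither lean passed. Without untreated EpiLC replicate 3 the p were 0.804 and 0.449, and Spearman's rho of the log2 changes across genes, which are not independent replicates, went from 0.08 to -0.08. The hypothesis was not borne out, and a shared change smaller than the spread of the EpiLC libraries stays open.

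Untreated EpiLC replicates 1 and 2 differed from replicate 3 by a chi-square per degree of freedom of 103 and 135, against 7.81 between each other. BPA PGCLC replicate 3 also stood apart, at 55.7 and 54.5 from replicates 1 and 2 against 4.13 between those, while untreated PGCLC replicates lay 18.9 to 22.6 apart. Gata4 was at 153, 159 and 43.9 CPM and Cubn at 1211, 1291 and 459 CPM in BPA PGCLC replicates 1, 2 and 3.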
